A study of Homo sapiens with 12 samples.

How the data were processed

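RNA was sequenced from 12 libraries of HCT116 and LoVo, established human colorectal cancer cell lines, with 3 libraries in each of 4 groups. Per the labels, HCT116 was given as a control and with overexpression of the long non-coding RNA SLERT, and LoVo as a control and with knockdown of SLERT. Per the labels' protocols, total RNA was taken with Trizol and 1 ug of it was used with an Illumina TruSeq RNA kit. The same protocol text speaks of retinas, whereas every other label names a colorectal cancer cell line, so it was not relied on for the tissue. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

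The deposited count table holds whole-number read counts for 62656 genes by Ensembl identifier, not normalised, as its values show. The deposited FPKM table holds values for 38828 genes, and each value equalled the count divided by gene length and by the column's total count, with a largest relative deviation of 4.44e-16 and 0 genes with counts left out. Reads were aligned with HISAT2 2.1.0 to GRCh38, per the submitters' processing notes. The read counter, the annotation release and whether counting used strand are not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart, and near-identical gene copies may share reads. This bears on ribosomal proteins, histones, metallothioneins, keratins and HLA genes, whose values are uncertain to that extent. The control columns of HCT116 are headed as empty vector in both tables, and their assignment to the HCT116 control rests on that heading beside the overexpression columns. It is the least certain mapping. The LoVo columns are headed Sh for the knockdown and ShNC for the control. Correlations of log2 CPM were at least 0.972 between the arms of a line and at most 0.714 between lines.

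Gene symbols were matched by identifier to GENCODE v29 and a table of gene names, which found 62639 of the identifiers, 42303 of them with a symbol. Coordinates are on GRCh38 from GENCODE v29. SLERT has no gene of its own among the symbols used here. As background, it is a long non-coding RNA with snoRNA ends, SNORA5A and SNORA5C, made from introns of TBRG4, so these 3 genes were used as the readout of its locus.

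Total counts per library ran from 14.46 to 17.23 M. Libraries of a group correlated at 0.991 to 0.996, and the chi-square per degree of freedom of their counts ran from 2.48 to 7.33 over the 12 pairs within groups, so no pair differed by less than sampling noise and each library was counted as 1 replicate. The 95% intervals of log2 fold changes come from the edgeR fit and include the spread between libraries. Floors cover only the counting error of the group with no counts. The counting intervals of MUC16 and SNORA5A cover counting error only, since reads without molecular identifiers are not independent molecules.

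Differential expression was tested per line with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, TMM factors and the filterByExpr filter, and Benjamini-Hochberg adjustment over all genes tested, with calls at an adjusted p under 0.05. The filter left 15980 genes in HCT116 and 16253 in LoVo, which held 99.8% of the counts in each. The common biological coefficient of variation was 6.00% and 6.41%. Levels are normalised counts per 1e6 counts (CPM), as mean ± SD over the 3 libraries of a group, and changes are log2 fold changes with their standard errors (SE). All 12 libraries were also fitted together, over 18199 genes, to test the difference and the mean of the changes with more SLERT in each line, overexpression minus control in HCT116 and control minus knockdown in LoVo. For a gene with no counts in a group, the fold is taken against a floor of 3 counts over that group.

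For gene groups, 36 lists were used, with markers of retina, leukocytes, fibroblasts and endothelium, and hepatocytes among them. They held 1013 symbols, of which 3 found no gene. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the lists of a line. Member counts are given over all genes tested and adjusted over the list alone. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took the genes of the SLERT locus, its partners and the series title, the 10 largest rises and falls per line among genes with an adjusted p under 0.05, an average log2 CPM of at least 1, a gene symbol and no overlap between arms, the 3 genes of each list with the smallest p, up to 6 genes per direction called in opposite directions, and the 6 genes with the smallest p for the difference between lines. A further check that the rule named is not reported here. With 3 libraries against 3, chance gives no overlap in 10% of genes (a share of 0.1).

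Alternatives were DESeq2 1.42.0, RLE and upper quartile factors, no filter and a stricter filter of at least 1 CPM in 3 libraries, limma voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), all 12 libraries in 1 fit, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a test against a fold of 1.2, and for lists an estimated correlation and fry. An adjusted p that DESeq2 did not give was not counted as a lost call. Other splits of the libraries were run as a check on chance.

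The procedure was tested on simulated counts with 200 genes changed by known folds. In the simulated HCT116 comparison of 15980 genes, 42.0%, 76.0%, 90.0% and 100% of the genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, and 11.0% of the calls were unchanged genes. In the simulated LoVo comparison of 16253 genes, the shares were 40.0%, 74.0%, 90.0% and 100%, and 7.88% of the calls were unchanged genes. With 18199 genes in the 12 libraries, 98.0% of genes changed 2-fold in both lines were found for the mean effect and 81.0% of those changed in HCT116 alone for the difference. Camera found the list that was raised 1.25-fold in each line and called 0 of the other lists. In this simulation the genes varied independently of each other. Ribosomal proteins in HCT116 had an estimated correlation of 0.869, so the simulation does not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.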

Results

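Gene expression was measured by RNA sequencing in 12 libraries, 3 each of HCT116 control cells, HCT116 cells with SLERT overexpression (OE), LoVo control cells and LoVo cells with SLERT knockdown (KD). HCT116 and LoVo are human colorectal cancer lines, and SLERT is a long non-coding RNA with snoRNA ends that is made from the TBRG4 locus. Total counts in the HCT116 controls were 17.23, 17.01 and 16.11 M, and in the HCT116 OE libraries 16.39, 16.54 and 15.3 M. The LoVo controls held 14.92, 14.95 and 14.46 M counts and the LoVo KD libraries 14.74, 16.11 and 15 M. Retina markers were not called by camera between the arms of HCT116 (5 measured, adjusted p = 0.715) or LoVo (8 measured, adjusted p = 0.598), which says nothing about the tissue. Of those measured in LoVo, BEST1 rose (log2 fold change 0.92), a call lost without 5 of the 6 libraries. In HCT116, leukocyte markers (7 measured, adjusted p = 0.317) and fibroblast and endothelial markers (5 measured, adjusted p = 0.979) were not called. Hepatocyte markers had 4 measured genes in HCT116 and 1 in LoVo, and leukocyte markers 1 in LoVo, too few for the test. Of these, HPX (log2 fold change -1.32) and CORO1A (-1.20) fell in LoVo with KD.

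The first comparison asked whether the manipulations changed the target itself. In HCT116 with OE, SNORA5C, a box H/ACA snoRNA that forms an end of SLERT, rose 125-fold, from 16 counts over the 3 controls to 1926 over the 3 OE libraries (0.320 ± 0.152 against 40.5 ± 6.76 CPM). SNORA5A, the snoRNA of the other end, had 0 counts in the controls and 142 in the OE libraries. This is 50.2-fold higher against a floor of 3 counts over the control group. The exact counting interval of its ratio, control over OE, ended at 0.0248. TBRG4, the host gene, rose 1.58-fold, from 162 ± 10.1 to 255 ± 13.8 CPM (log2 fold change 0.66, SE 0.058). The edgeR adjusted p was 3.50e-19 for SNORA5C, 1.42e-07 for SNORA5A and 5.24e-08 for TBRG4, and each was higher in 3 of 3 OE libraries than in any control. TBRG4 (ENSG00000136270) lies on the minus strand of chromosome 7 at 45100100 to 45112047 (GRCh38). SNORA5C (ENSG00000201772, 45104906 to 45105042) sits in its intron between exons 3 and 4, and SNORA5A (ENSG00000206838, 45104349 to 45104482) in the intron between exons 4 and 5. Exon 4 lies between them, so a transcript that spans both would also give reads to TBRG4. SNORA5B, a further snoRNA of the locus, had 0 counts in all 12 libraries, which allows up to 3 counts in each.

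In LoVo, no fall was found for any of the 3 genes of the locus in the libraries labelled SLERT knockdown. SNORA5C had 37 counts over the 3 controls and 37 over the 3 KD libraries (0.834 ± 0.413 against 0.816 ± 0.0606 CPM), and its log2 fold change of -0.02 had a 95% interval from -0.92 to 0.87 (edgeR adjusted p = 0.980), so a fall by a factor of 2 stays open, with a lower end of -1.23 without control 1. Its sign depended on single libraries, with a log2 fold change of 0.45 without control 3 and 0.02 without KD 1. SNORA5A had 12 and 10 counts. TBRG4 stood at 225 ± 2.91 and 236 ± 16.6 CPM (log2 fold change 0.07, 95% interval -0.05 to 0.20, adjusted p = 0.413). SLERT is made from introns of this gene, so TBRG4 need not follow SLERT, and the readout rests mainly on the few snoRNA counts. Directions below are therefore given for the libraries by their label. NUDCD3, another gene on chromosome 7, did not pass the test in HCT116 (log2 fold change -0.02, adjusted p = 0.913) and stood at 188 ± 4.80 and 169 ± 1.27 CPM in LoVo (adjusted p = 0.0577).

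**Figure D1:**
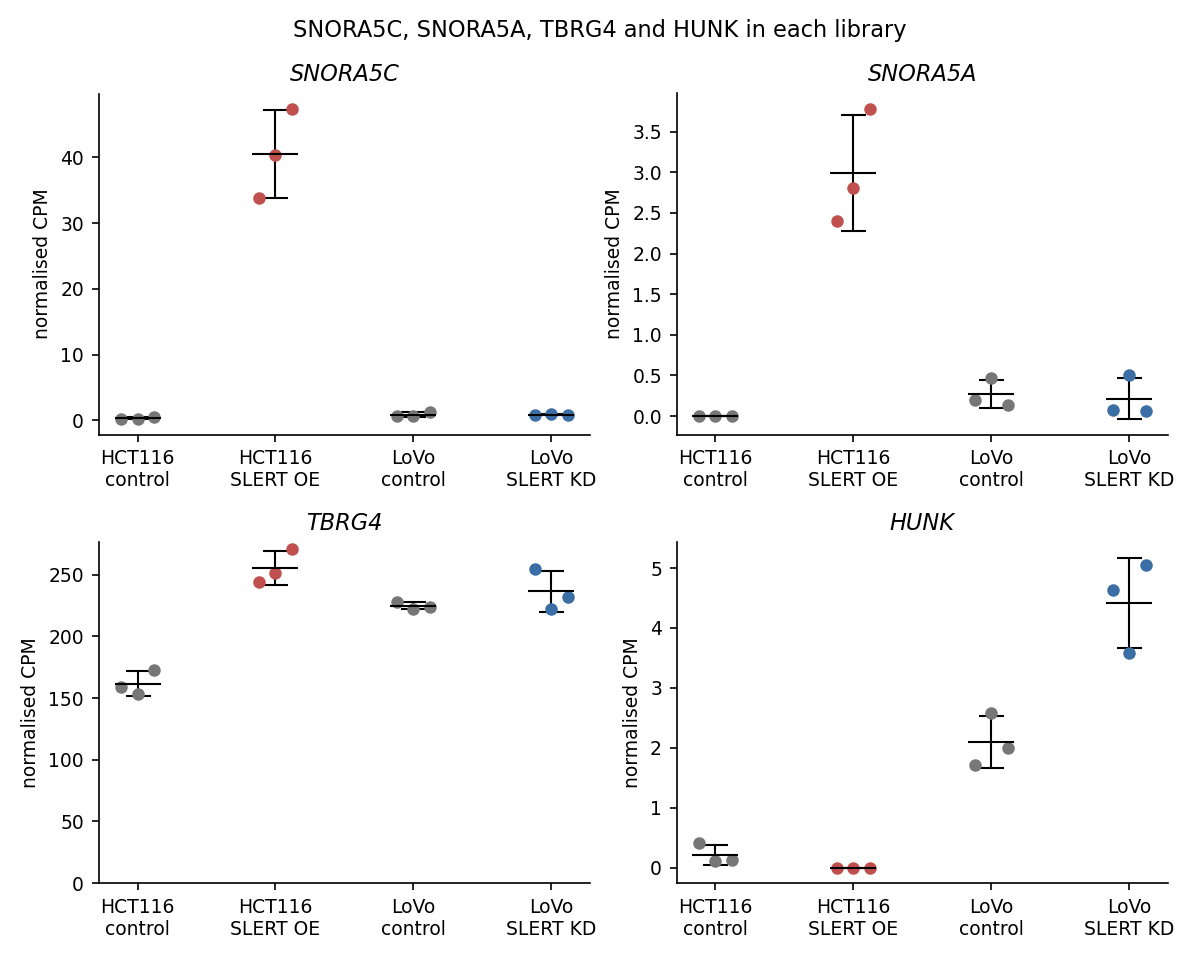
Normalised CPM of genes of the SLERT locus and of HUNK per library in HCT116 control, HCT116 SLERT overexpression (OE), LoVo control and LoVo SLERT knockdown (KD); points are libraries, lines are group means and bars are SD (n = 3). SNORA5C is at 40.5 CPM with OE against 0.320 in its control, and at 0.816 against 0.834 CPM in the LoVo libraries.

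The comparison within HCT116 asked which genes respond to more SLERT. Besides the locus itself, the rises were small. WDR76, a nuclear WD-repeat protein, rose 1.33-fold (39.0 ± 1.15 to 51.9 ± 2.41 CPM), SPC25, a subunit of the kinetochore NDC80 complex, rose 1.35-fold (28.0 ± 0.281 to 37.9 ± 2.14 CPM), and AIFM2, a suppressor of ferroptosis, rose 1.32-fold (37.3 ± 2.16 to 49.0 ± 1.31 CPM). The clearest fall was that of NDRG1, a gene induced by hypoxia and known as a metastasis suppressor, from 363 ± 12.9 to 236 ± 12.03 CPM (log2 fold change -0.62, SE 0.054, edgeR adjusted p = 5.24e-08). ARRDC4, an alpha-arrestin (log2 fold change -0.55, SE 0.093), TNXB, which encodes tenascin-X (-0.51, SE 0.088), RCAN2, a regulator of calcineurin (-0.78, SE 0.16), and KRBOX5, a KRAB-domain gene (-0.60, SE 0.11), fell as well. AUNIP, MT1E, ARPC4, EXO1 and TIMM13 rose by 0.37 to 0.48 on the log2 scale, and MUC12, NFATC4, LRRC37B, ACAP1 and KANSL1L had log2 fold changes from -0.74 to -0.53. MT1E is 1 of several similar metallothionein genes, and its reads may be shared with them.

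In all, 146 of 15980 genes were called in HCT116 by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 81 higher and 65 lower with OE. Only 3 of the 146 changed 2-fold or more, and the median size of the called changes was 0.31 on the log2 scale. The share of higher calls was 55.5%, and it moved to 41.8% of 141 with upper quartile factors, 69.8% of 281 with DESeq2 and 44.0% of 109 with all 12 libraries in 1 fit. Without a filter 256 genes were called, on log2(FPKM + 1) 7 and on log2(FPKM + 0.1) 7. The count was 37 without control 1, 38 without control 2, 287 without control 3, 43 without OE 2 and 37 without OE 3. The calls of TBRG4, SNORA5C, SNORA5A, NDRG1, WDR76, ARRDC4 and TNXB held whichever of the 6 libraries was left out, whereas that of SPC25 was lost without OE 3 (log2 fold change 0.39), AIFM2 without control 1 (0.36), KRBOX5 without OE 2 (-0.56) and RCAN2 without control 1 (-0.82) and OE 2 (-0.73). AUNIP, MT1E, ARPC4, EXO1, TIMM13, MUC12, NFATC4, LRRC37B, ACAP1 and KANSL1L each lost the call without at least 2 of the 6 libraries.

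Genes of G1/S and DNA replication rose together in HCT116 with OE. All 40 measured members had a positive log2 fold change, with a median of 0.25, and 18 of them rose, or 35 adjusted over the list alone. MCM4, a subunit of the replicative helicase, rose from 290 ± 1.78 to 370 ± 1.99 CPM (log2 fold change 0.35, SE 0.050, adjusted p = 0.000278), and UHRF1, which maintains DNA methylation at replication (0.36, SE 0.055), and MCM5, of the same helicase (0.35, SE 0.055), rose alike. The list was called by camera (adjusted p = 6.43e-24) and was the only list of the 35 tested in HCT116 called with an estimated correlation too (adjusted p = 0.00875). MYC targets rose as a list, with 8 of 34 members past the test and 18 adjusted over the list alone (median 0.18, adjusted p = 0.0724 with an estimated correlation), among them PCNA, the replication clamp (0.27, SE 0.052). MCM2, MCM4, MCM5 and PCNA also stand in the G1/S list and HSPD1 in the heat shock list, and each of them was called. The rise of MYC targets is therefore not independent of those lists. Ribosome biogenesis factors rose, with 6 of 40 members past the test and 15 adjusted over the list alone (median 0.13, adjusted p = 0.0765 with an estimated correlation), among them MRTO4 (0.29), NIP7 (0.32) and PES1 (0.24). Heat shock proteins rose, with 3 of 19 members past the test and 12 adjusted over the list alone (median 0.18, adjusted p = 0.0654 with an estimated correlation), namely HSPD1 (0.21), HSPA8 (0.19) and FKBP4 (0.21), which are chaperones and a co-chaperone.

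Further lists were called in HCT116 with few or no single genes past the test. The RNA polymerase I list was called upward with 0 of 25 members by edgeR and 1 adjusted over the list alone (median 0.14, adjusted p = 0.0945 with an estimated correlation), and NCL, which encodes nucleolin, had a log2 fold change of 0.17 (adjusted p = 0.0719). G2/M and mitosis genes were called upward with 0 of 38 members and 2 adjusted over the list alone (median 0.08, adjusted p = 0.273 with an estimated correlation). Nuclear-encoded oxidative phosphorylation was called upward with 0 of 41 members and 0 adjusted over the list alone (median 0.11, adjusted p = 0.616 with an estimated correlation), and so were cytosolic ribosomal proteins with 0 of 46 members and 0 adjusted over the list alone (median 0.06, adjusted p = 0.781 with an estimated correlation), where reads may be shared between copies. Without control 3, 3 oxidative phosphorylation genes and 7 ribosomal protein genes passed. The list of the SLERT locus and its partners was called upward with 3 of 6 members and 4 adjusted over the list alone (adjusted p = 0.0724 with an estimated correlation). The 3 are SNORA5C, SNORA5A and TBRG4 of the overexpressed locus itself, so this call is no further result. Immediate early genes, which respond to growth factors and stress, fell as a list, with 4 of 36 members past the test and 16 adjusted over the list alone (median -0.13, adjusted p = 0.471 with an estimated correlation), among them FOSB (-0.37), NR4A1 (-0.32) and NR4A2 (-0.37). Hypoxia and glycolysis genes fell, with 4 of 38 members past the test and 9 adjusted over the list alone (median -0.06, adjusted p = 0.505 with an estimated correlation), among them NDRG1, the aldolase gene ALDOC (-0.47) and the collagen hydroxylase gene P4HA1 (-0.32). Lists named by the study's subject were not called, with 0 of 22 writers, erasers and readers of m6A past the test (camera adjusted p = 0.589), 0 of 19 mesenchymal genes (adjusted p = 0.0788) and 0 of 27 epithelial genes (adjusted p = 0.323). Adjusted over the list alone, 0, 3 and 4 of them fell, and fry called the mesenchymal list downward (adjusted p = 0.0232).

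In total 11 of the 35 lists were called in HCT116, 9 upward, the SLERT list included, and 2 downward. Of the 10 that fry called, 6 were among them, and it did not call cytosolic ribosomal proteins (adjusted p = 0.690), oxidative phosphorylation (0.399), immediate early genes (0.0975), hypoxia (0.0823) or G2/M genes (0.0736). With an estimated correlation 1 was called, and this gave the highest adjusted p of the 11 alternatives for each called list. The lowest adjusted p over the alternatives ran from 8.06e-24 for G1/S to 0.00327 for hypoxia. Counts of members past the test depended on single libraries. G1/S genes past it numbered 6 without control 1, 5 without control 2, 6 without OE 2 and 7 without OE 3, and MYC targets 3, 2, 2 and 2. Ribosome biogenesis factors numbered 0, 0, 1 and 0 in the same fits, heat shock proteins 0 in each, and immediate early genes 0, 2, 1 and 2, all by edgeR. Hypoxia genes numbered 2 without control 1, control 2 or OE 3, and the list was not called without OE 2 (adjusted p = 0.173). The ribosomal protein list was not called without control 1 (adjusted p = 0.596), control 2 (0.493), OE 2 (0.128) or OE 3 (0.628), nor oxidative phosphorylation without OE 3 (0.0525).

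**Figure D2:**
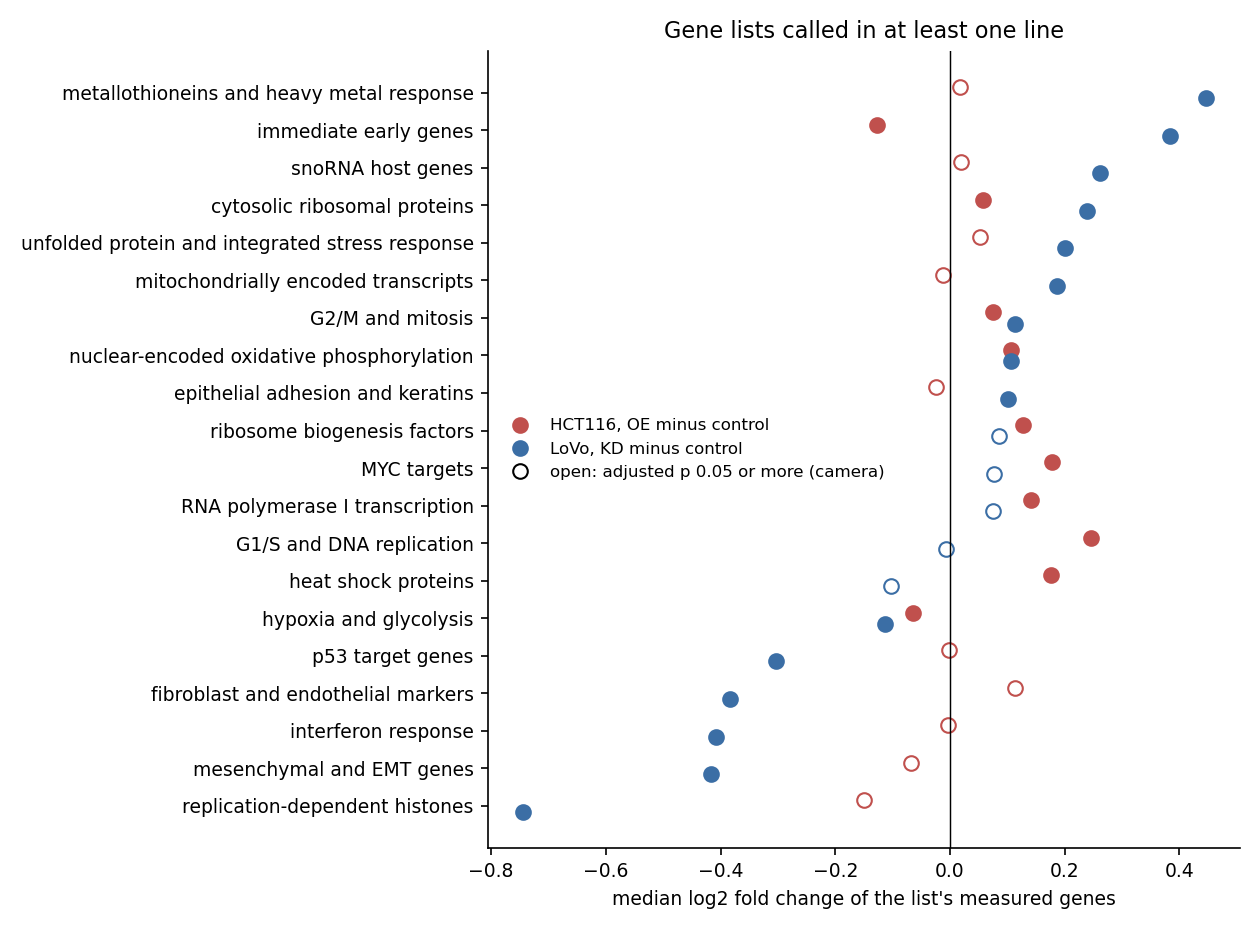
Median log2 fold change of the genes of each list called in at least 1 line, in HCT116 (OE against control) and LoVo (KD against control), with filled points for lists with an adjusted p under 0.05 by camera; the list of the SLERT locus is left out. G1/S and DNA replication genes are at 0.25 in HCT116 and -0.01 in LoVo, and interferon response genes at -0.41 in LoVo.

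The series title puts HUNK, an AMPK-related protein kinase, below SLERT, with RBM15, a component of the m6A methyltransferase complex, as the link. In LoVo, HUNK rose 2.09-fold in the libraries labelled SLERT knockdown, from 2.1 ± 0.438 to 4.42 ± 0.755 CPM (log2 fold change 1.07, SE 0.23, n = 3, edgeR adjusted p = 0.00167). It had 26 to 39 counts per control and 57 to 75 per KD library, and 3 of 3 KD libraries lay above every control. Its adjusted p over the alternatives ran from 0.000137 to 0.0270. In HCT116, HUNK was near the limit of detection, with 7, 2 and 2 counts in the controls (0.215 ± 0.164 CPM) and 0 in each OE library. Against a floor of 3 counts over the OE group it was 3.46-fold lower, or 1.91-fold without control 1. The floor leaves out the counting error of the controls, so these folds are not lower bounds. The exact permutation test on CPM, two-sided, gave p = 0.1, the smallest that 3 libraries against 3 allow. The filter on low counts kept HUNK out of the edgeR test in HCT116, and over the other fits its adjusted p ran from 0.0417 with limma voom without a filter to 0.763 on log2(FPKM + 1). With all 12 libraries in 1 fit, the mean effect of more SLERT on HUNK was negative (edgeR adjusted p = 0.00447), and the adjusted p for a difference between the lines was 0.0816. HUNK (ENSG00000142149) lies on chromosome 21 at 31873315 to 32044633, on the plus strand.

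RBM15 (ENSG00000162775, chromosome 1, 110338506 to 110346681) did not pass the test in HCT116 (54.4 ± 3.71 and 51.4 ± 5.66 CPM, log2 fold change -0.08, SE 0.079, adjusted p = 0.695) or in LoVo (30.5 ± 0.486 and 32.6 ± 0.583 CPM, log2 fold change 0.10, SE 0.082, adjusted p = 0.410). DDX21 (ENSG00000165732, chromosome 10, 68956128 to 68985073), an RNA helicase of the nucleolus that SLERT is known to bind, rose in LoVo with KD from 374 ± 6.44 to 458 ± 14.5 CPM (log2 fold change 0.29, SE 0.054, adjusted p = 0.000324), and in HCT116 stood at 349 ± 12.9 and 386 ± 19.7 CPM (log2 fold change 0.14, SE 0.054, adjusted p = 0.195). Of 22 m6A writers, erasers and readers in LoVo, YTHDC2, a reader, rose (0.31, SE 0.070) and the demethylase ALKBH5 fell (-0.22, SE 0.066), while the list was not called (camera adjusted p = 0.366). The call of ALKBH5 was lost without control 3 (-0.19), KD 2 (-0.18) or KD 3 (-0.23), and 4 genes of the list rose without KD 1.

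The comparison within LoVo asked which genes differ with the label of SLERT knockdown, and it held far more changes than HCT116. Immediate early transcription factors rose most, of the genes named by the fixed rule, in the libraries labelled SLERT knockdown. FOS rose 8.56-fold (24.6 ± 3.78 to 210 ± 13.6 CPM, log2 fold change 3.10, SE 0.087), EGR1 rose 7.02-fold (74.9 ± 9.33 to 526 ± 49.1 CPM, 2.81, SE 0.081), and FOSB rose 5.68-fold (8.37 ± 2.16 to 47.6 ± 0.847 CPM, 2.51, SE 0.12). MUC16, a transmembrane mucin, went from 299 counts over the controls to 3 over the KD libraries, a ratio of 100.8 with a counting interval from 34.2 to 492. KRT4, a keratin (log2 fold change -3.67, SE 0.13), TIMP3, an inhibitor of metalloproteinases (-3.64, SE 0.23), NOS2, the inducible nitric oxide synthase (-3.57, SE 0.18), COL13A1, a transmembrane collagen (-3.55, SE 0.34), and HLA-DRA, an MHC class II chain (-3.46, SE 0.35), fell more than 8-fold. AQP1 (-3.42), KRT5 (-2.78), the imprinted RNA H19 (-2.60) and CD74, the MHC class II invariant chain (-2.59), fell too. Further rises were those of EGR2 (2.05), NHS (1.90), RADX (1.49), GPRC6A (1.46), the chemokine gene CXCL3 (1.45), SERTAD4 (1.43) and AGR2, a protein disulfide isomerase of secretory epithelium (1.40). The call of EGR2, at 0.739 ± 0.699 CPM in the controls, was lost in DESeq2 (2.07).

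In LoVo, 4278 of 16253 genes were called by edgeR, 2050 higher and 2228 lower with KD, and 380 of them changed 2-fold or more, 119 upward and 261 downward. The share of higher calls was 47.9%, and on log2(FPKM + 1) it was 34.0% of 2845. The count was 2809 without control 1 and 2769 without control 3. Mitochondrially encoded genes held 5.09% to 5.53% of the counts in the controls and 5.79% to 6.15% in the KD libraries.

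Interferon response genes and p53 targets fell in LoVo with KD. Of 41 interferon genes, 25 fell and 1 rose, or 32 and 1 adjusted over the list alone (median -0.41, camera adjusted p = 3.16e-12, adjusted p = 0.0740 with an estimated correlation), among them the antiviral genes IFIT1 (-1.55, SE 0.11), OASL (-1.26, SE 0.079) and IFIT3 (-1.13, SE 0.084). Of 30 p53 targets, 18 fell and 2 rose, the same numbers adjusted over the list alone (median -0.30, camera adjusted p = 2.03e-06, adjusted p = 0.0740 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fell from 172 ± 5.18 to 70.4 ± 1.95 CPM (log2 fold change -1.29, SE 0.063), and PHLDA3 (-0.92) and TP53INP1 (-1.17) fell with it. Of 21 mesenchymal genes, 8 fell, and 8 adjusted over the list alone (median -0.42, adjusted p = 0.286 with an estimated correlation), among them COL3A1, a fibrillar collagen (-2.57), TNC, tenascin-C (-1.26), and TAGLN (-0.74). The fibroblast and endothelial markers were called downward with 2 of 6 members, COL3A1 and ENG (-0.51), and 2 adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). Replication-dependent histones were called downward with 3 of 10 members and 4 adjusted over the list alone (median -0.75, adjusted p = 0.286 with an estimated correlation), namely H2AC6 (-0.87), H2BC5 (-1.15) and H1-2 (-0.69), whose reads may be shared between copies. Of 37 hypoxia and glycolysis genes, 12 fell and 4 rose, or 15 and 5 adjusted over the list alone (median -0.11, adjusted p = 0.363 with an estimated correlation), with falls of the glucose transporter SLC2A3 (-0.95), ADM (-0.89) and PFKFB3 (-0.50).

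Genes of translation, immediate early genes and genes of the unfolded protein and integrated stress responses rose in LoVo with KD. Of 46 cytosolic ribosomal protein genes, all with a positive log2 fold change, 36 rose, or 42 adjusted over the list alone (median 0.24, camera adjusted p = 2.32e-09, adjusted p = 0.402 with an estimated correlation), among them RPL22 (0.42), RPL4 (0.31) and RPS6 (0.33), with reads that copies may share. Of 18 snoRNA host genes, 9 rose, or 11 adjusted over the list alone (median 0.26, adjusted p = 0.365 with an estimated correlation), among them SNHG1 (0.44), SNHG8 (0.56) and SNHG29 (0.37). Of 36 immediate early genes, 18 rose and 4 fell, or 20 and 4 adjusted over the list alone (median 0.38, camera adjusted p = 2.03e-06, adjusted p = 0.286 with an estimated correlation). Of 37 genes of the unfolded protein and integrated stress responses, 20 rose and 2 fell, or 22 and 3 adjusted over the list alone (median 0.20, adjusted p = 0.269 with an estimated correlation), among them DDIT4 (0.64), XBP1, a transcription factor of the unfolded protein response (0.46), and the seryl-tRNA synthetase gene SARS1 (0.44). Of 8 metallothionein and metal response genes, 4 rose and 1 fell, and likewise adjusted over the list alone (median 0.45, adjusted p = 0.286 with an estimated correlation), with MT1E at 1.36, MT2A at 0.99 and the zinc exporter SLC30A1 at 0.55. Heat shock proteins, by contrast, had 6 of 19 members lower and 1 higher, or 7 and 1 adjusted over the list alone (median -0.10), with falls of BAG3 (-0.68), HSPA1B (-0.61) and SERPINH1 (-0.48), and the list was not called by camera (adjusted p = 0.0580, from 0.00620 to 0.341 over the alternatives). The higher ones numbered 0 without control 1, control 3, KD 2 or KD 3, and 2 without KD 1.

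Smaller shifts were called for the cell cycle, the mitochondria and the epithelium in LoVo. Of 39 G2/M genes, 11 rose, or 12 adjusted over the list alone (median 0.11, adjusted p = 0.365 with an estimated correlation), among them ECT2 (0.35), HMMR (0.34) and TOP2A (0.24). Of 15 mitochondrially encoded transcripts, 7 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.472 with an estimated correlation), among them MT-CO1 (0.22), MT-CO2 (0.26) and MT-RNR2 (0.24). Of 41 nuclear-encoded oxidative phosphorylation genes, 8 rose, and 8 adjusted over the list alone (median 0.11, adjusted p = 0.544 with an estimated correlation), among them COX6C (0.47). Of 28 epithelial adhesion and keratin genes, 11 rose and 6 fell, or 11 and 7 adjusted over the list alone (median 0.10, adjusted p = 0.312 with an estimated correlation), and CDH17, an intestinal cadherin (0.78), CLDN4 (0.73) and ELF3 (0.56) rose. G1/S genes were not called in LoVo, with 1 of 40 higher and 6 lower (median -0.01, camera adjusted p = 0.943), and without control 1, control 3 or KD 3 the lower ones numbered 2, 3 and 3, and without KD 1 and KD 2 the higher ones 5 and 3.

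In total 15 of the 34 lists tested in LoVo were called, 9 upward and 6 downward. Of the 22 that fry called, 13 were among them, and it did not call oxidative phosphorylation (adjusted p = 0.192) or mitochondrially encoded transcripts (0.0688). With an estimated correlation camera called 0, with an unadjusted p under 0.05 for 4 lists, and this alternative gave the highest adjusted p for each called list. The lowest adjusted p over the alternatives ran from 7.16e-14 for the interferon list to 0.00703 for oxidative phosphorylation. Without control 1, 22 ribosomal protein genes, 5 G2/M genes and 1 oxidative phosphorylation gene passed, and without control 3 it was 6 G2/M, 3 oxidative phosphorylation and 2 higher hypoxia genes and 2 lower immediate early genes. Without KD 3, 5 oxidative phosphorylation and 2 higher hypoxia genes passed. The hypoxia list was not called without control 1 (adjusted p = 0.114), oxidative phosphorylation without control 1 (0.156) or KD 2 (0.114), the epithelial list without control 2 (0.0784), KD 1 (0.105) or KD 3 (0.0550), and the fibroblast list without control 2 (0.0625) or KD 3 (0.137). ENG lost its call without 5 of the 6 libraries, with log2 fold changes from -0.54 without control 1 to -0.46 without control 3, and H1-2 without KD 2 (-0.52).

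**Figure D3:**
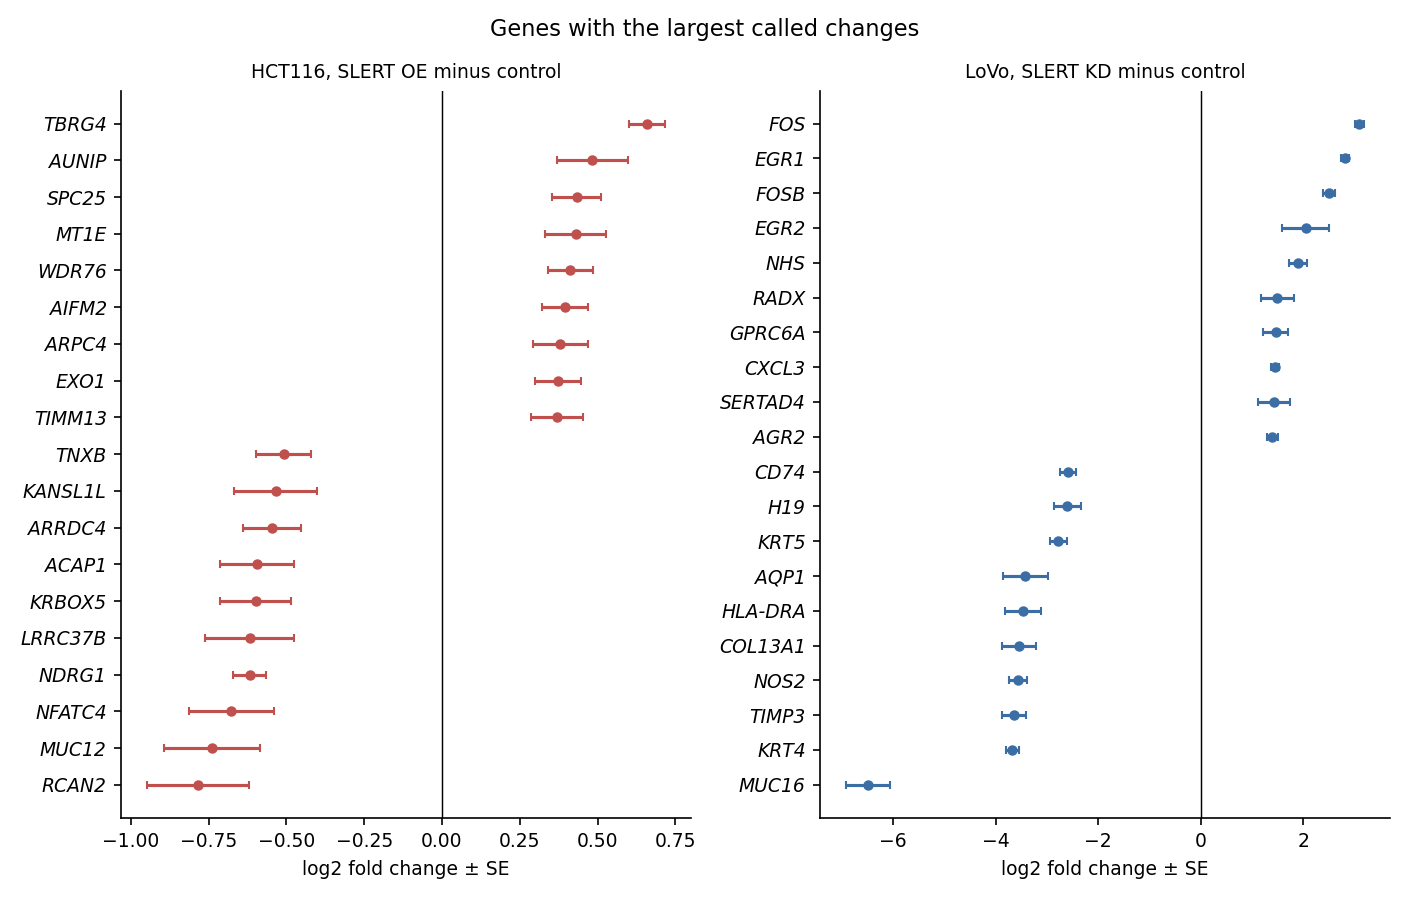
Log2 fold change with its standard error of the genes named by size in HCT116 (OE against control) and LoVo (KD against control); points are edgeR estimates from 3 libraries per group, and SNORA5C is left out. FOS is at 3.10 in LoVo and NDRG1 at -0.62 in HCT116.

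Opposite changes would be sought for genes that follow SLERT in both lines. Among 14217 genes tested in both, 141 were called in HCT116 and 3967 in LoVo, and 29 were called in opposite directions with OE and KD, where independent lists give 19.8. In the same direction 21 were called, where independent lists give 19.6. The transcription factor genes FOSB (-0.37 with OE, 2.51 with KD), NR4A2 (-0.37, 0.75) and NR4A1 (-0.32, 0.56), the polyamine enzyme gene SAT1 (-0.46, 0.39), ZC3H6 (-0.46, 0.52) and MCF2L (-0.34, 0.43) fell with OE and rose with KD. The chromatin and cell cycle genes UHRF1 (0.36, -0.53), ASF1B (0.27, -0.33) and MYBL2 (0.26, -0.45), and DYNC2I2 (0.31, -0.31), ANXA3 (0.30, -0.34) and SNRNP25 (0.37, -0.27) rose with OE and fell with KD. With a library left out, the calls of SAT1 and UHRF1 held in both lines. In HCT116, calls were lost for FOSB without control 1 (-0.31), NR4A1 without control 1 (-0.23) and OE 2 (-0.28), and NR4A2 without control 1 (-0.26), control 2 (-0.42), OE 2 (-0.35) and OE 3 (-0.33). That of MCF2L was lost without control 1 (-0.32), control 2 (-0.34), OE 2 (-0.27) and OE 3 (-0.38), that of DYNC2I2 without control 1 (0.29), control 2 (0.28) and OE 3 (0.32), and that of ANXA3 without control 1 (0.26), control 2 (0.33), OE 2 (0.22) and OE 3 (0.33). That of MYBL2 was lost without control 1 (0.26), control 2 (0.26), OE 1 (0.20) and OE 3 (0.27), those of ZC3H6 (-0.48 to -0.42) and ASF1B (0.23 to 0.30) without any 1 of 5 libraries, all but control 3, and that of SNRNP25 without any 1 of the 6 (0.32 to 0.44). In LoVo, calls were lost for ANXA3 without control 3 (-0.27) and for SNRNP25 without control 2 (-0.20), control 3 (-0.27) and KD 3 (-0.17), and with DESeq2 (-0.26). Of the 4 pairings of directions, lower with OE and higher with KD held 15 genes where 8.16 were expected (odds ratio 2.12, Fisher's exact test, two-sided, p = 0.0212, adjusted p = 0.0844). Lower in both held 15 where 8.86 were expected (exact adjusted p = 0.0844), higher with OE and lower with KD 14 where 11.6 were expected (adjusted p = 0.427), and higher in both 6 where 10.7 were expected (adjusted p = 0.185). No pairing passed the adjustment. The number of opposite genes was 7 without HCT116 control 1, 9 without HCT116 control 2, 11 without OE 2, 8 without OE 3, 16 without LoVo control 3 and 17 without KD 3.

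Across the 14217 genes, the changes with more SLERT in HCT116 and in LoVo correlated at -0.0725 (Pearson) and -0.0735 (Spearman), a correlation over genes, which are not independent replicates. It was -0.0370 without HCT116 control 1, -0.0964 without OE 1 and -0.0253 without OE 2. In the fit of all 12 libraries, 2119 of 18199 genes had a mean effect of more SLERT that passed the edgeR test, 1097 higher and 1022 lower, which a large change in LoVo alone can give. In the same fit, 2648 had effects that differed between the lines, 1263 higher and 1385 lower in HCT116 than in LoVo. The strongest differences by p were those of FOS (-0.23 with OE in HCT116, -3.10 for control minus KD in LoVo), EGR1 (-0.18, -2.82), LRP1 (-0.44, 1.59), FOSB (-0.37, -2.51), CDKN1A (0.10, 1.28) and TIMP3 (-0.15, 3.64).

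**Figure D4:**
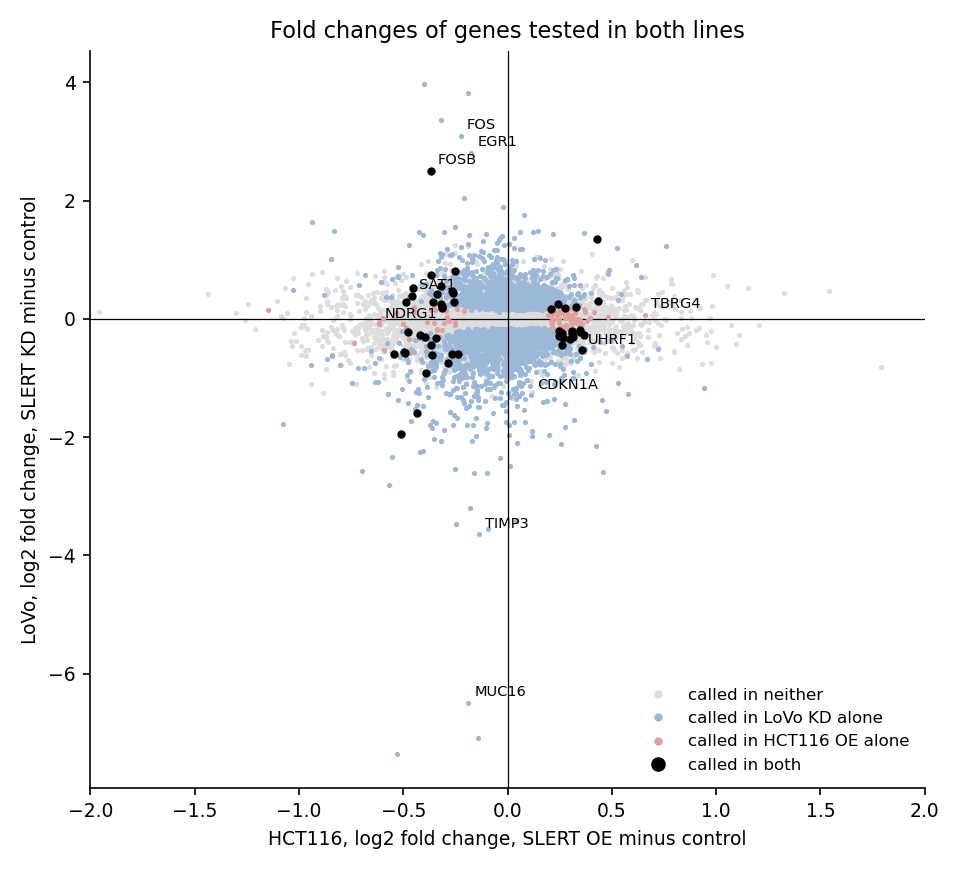
Log2 fold change with OE in HCT116 (x axis) against log2 fold change with KD in LoVo (y axis) for 14217 genes tested in both lines, each point a gene and black points genes called in both; SNORA5C lies outside the x axis and is left out. The black points hold 29 genes in opposite and 21 in the same directions.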

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

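The tests of handling that varied from dish to dish and of a trend on GC content and gene length for single lists, and the limit to splits with whole LoVo arms, were chosen only after the results were seen. The results below were singled out because a test of the difference between the lines passed, with changes taken as more SLERT against less in both lines. In LoVo no fall of the SLERT locus was seen, so the direction there rests on the label.

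The fit of all 12 libraries found 2648 genes whose effect differed between HCT116 and LoVo. By the smallest p, these were FOS, with a difference of 2.87 on the log2 scale, EGR1 (2.635), LRP1 (-2.032), FOSB (2.138), CDKN1A (-1.174) and TIMP3 (-3.785). In each of the 6, the change in LoVo was the larger.

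Lists differed too by camera with its preset correlation, given here as the mean difference in log2 fold change of their genes. Higher or lower in HCT116 names the change with more SLERT in HCT116 against that in LoVo, and not the change in HCT116 itself. Immediate early genes had a mean change of -0.1351 in HCT116 and -0.6921 in LoVo, and mesenchymal genes -0.02671 and 0.7721. For G1/S genes the means were 0.2366 and 0.001222. Of the lists still under 0.05 with an estimated correlation, higher in HCT116 were G1/S and DNA replication (0.2354), MYC targets (0.189) and ribosome biogenesis factors (0.1955). The unfolded protein and integrated stress responses (0.2349) and the SLERT locus and partners (1.784) were higher too. The last list holds the overexpressed locus itself. Lower in HCT116 were interferon response (-0.7556), mesenchymal genes (-0.7988) and p53 targets (-0.3369). The other lists were not under 0.05 with an estimated correlation. Among them, higher in HCT116 were cytosolic ribosomal proteins (0.3018), G2/M and mitosis (0.171), immediate early genes (0.557), metallothioneins (0.5495), mitochondrially encoded transcripts (0.1549), oxidative phosphorylation (0.2077), RNA polymerase I transcription (0.1349) and snoRNA host genes (0.2503). Lower in HCT116 were hepatocyte markers (-1.621), hypoxia and glycolysis (-0.2803), proteases and integrins (-0.3437), replication-dependent histones (-0.7313) and Wnt targets (-0.2279).

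The rise of G1/S and DNA replication genes in HCT116 with overexpression was weighed against technical explanations. Against a trend on GC content and gene length as the whole cause stood that its removal left the median log2 fold change of the list at 0.2612 from 0.245 (SD over members 0.0739). The share of reads from non-coding genes was 1.49% to 1.55% in the controls and 1.44% to 1.46% with OE. A shift of that size argued against a lower non-coding share as the cause. The excess of 0.2277 over protein-coding genes of the same expression could hardly have come out otherwise and adds little. What stays open is a difference in growth or density between the dishes of the arms, which no table here can separate from SLERT. Whether the cells cycled faster was not measured.

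The rise of immediate early genes in LoVo with knockdown was weighed in the same way. Removal of the trend on GC content and gene length left the median at 0.4407 from 0.383, which argued against that trend as the whole cause. Handling that varied from dish to dish cannot be told apart from the knockdown, since the labels do not say whether the libraries of an arm came from separate dishes, although their larger range was 23.39% of the difference between arms. Handling shared by a whole arm stays open too, because immediate early genes respond within minutes to medium and temperature. The biological explanation, a response to the knockdown, stays open beside it.

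Other splits of the libraries were counted against the real one. In HCT116, the real split gave 146 genes and the highest other split 139, and for lists 11 and 9, with 1 of 10 splits, the real one itself, as large in both. That other split exchanged control 3 and overexpression 1, and its smallest p-values belonged to U2AF1, RPS12, RPS28 and RPLP1. Every other split keeps part of the real contrast, so its list count is no pure chance value. In HCT116, camera called G1/S genes in each of them (adjusted p from 0.00176 to 0.0185). In LoVo, the real split gave 4278 genes and the highest other 0, and for lists 15 and 7, again with 1 of 10, the real one. With 10 splits per line, the splits are too few for a share under 0.05. Genes called in opposite directions numbered 29, and 2 of 200 pairs of splits, the real one included, gave as many, with 55 in the highest other. For the difference between lines, 1 of 100 splits gave as many as 2648 genes, with 2444 in the highest other, and for the mean effect 3 of 100 gave as many as 2119, with 2648 in the highest other. That last split exchanged the arms of LoVo as a whole, which turns the mean into the difference, so its 2648 is the real count of differences and no chance value. With the LoVo arms mixed, no genes were called in opposite directions, and at most 4 and 3 for the difference and the mean effect, so those splits were fixed near 0 by LoVo. Only 20 pairs and 11 splits left the LoVo arms whole, and these are too few for a share under 0.05 for all 3 results.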

How the results depend on the processing

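All alternatives here were chosen before the data were examined, apart from the removal of the trend on GC content and gene length. In HCT116, 146 genes were called, against 281 with DESeq2, 256 without a filter, 7 on log2(FPKM + 1), 7 on log2(FPKM + 0.1), 5 against a fold of 1.2 and 33 at an adjusted p under 0.01, and 37 to 287 with a library left out. In LoVo, 4278 were called, against 2845 on log2(FPKM + 1), 914 against a fold of 1.2, 2455 at an adjusted p under 0.01 and 2769 to 4813 with a library left out. The 29 genes called in opposite directions were 47 with DESeq2, 0 on log2(FPKM + 1), 0 on log2(FPKM + 0.1) and 7 to 36 with a library left out. At an unadjusted p under 0.05, edgeR had 2298 genes in HCT116 and 6077 in LoVo. The correlation between lines was -0.1041 among genes called in either line, and -0.09639 to -0.02526 with a library left out. A stricter threshold on p or fold calls fewer genes by construction, and for the other settings the cause was not tested.

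With an estimated correlation, camera called 1 list in HCT116 and 0 in LoVo, against 11 and 15 with the preset one. By fry 10 and 22 were called, of which 6 and 13 were among these. RLE factors gave 11 and 15, the stricter filter 12 and 14, and leaving out a library 9 to 12 and 13 to 16. After removal of the trend on GC content and gene length, 11 and 14 lists were called, 10 and 11 of them called before as well. It ended the calls of ribosomal proteins in HCT116 (adjusted p = 0.0991) and of G2/M (0.116), hypoxia (0.116), mitochondrially encoded (0.205) and fibroblast (0.116) lists in LoVo, and the cause was not tested. It added calls of the unfolded protein and integrated stress list in HCT116 (0.0454) and, in LoVo, of heat shock proteins (0.0230), ribosome biogenesis (0.0230) and the SLERT list (0.0398). The fibroblast and endothelial list had too few genes in LoVo under the stricter filter.

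Signs turned only for genes near 0 among those named. The log2 fold change of NUDCD3 HCT116 OE ran from -0.06399 (without HCT116 SLERT OE replicate 3) to 0.004529 (without HCT116 SLERT OE replicate 2), with 0.0003753 without replicate 1. That of RBM15 HCT116 OE ran from -0.1409 (without HCT116 SLERT OE replicate 2) to 0.005212 (without HCT116 SLERT OE replicate 3), and SNORA5C in LoVo from -0.213 to 0.4519 (0.02405 without KD 1). SNORA5C in LoVo was 0.02317 on log2(FPKM + 1). The cause was not tested. Named genes other than HUNK were run under DESeq2, RLE factors, no filter, log2(FPKM + 1), the replicate block and each library left out. Of 51 called in HCT116, 5 were called under all of these, namely TBRG4, SNORA5C, SNORA5A, NDRG1 and MCM4, the snoRNAs without an adjusted p from DESeq2. The other 46 were lost on log2(FPKM + 1). Over all 51, 130 of the 306 values with a library left out were lost. In LoVo, 104 of 119 were called under all of these alternatives. Over all 119, 23 of the 714 values with a library left out were lost.

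With the replicate number as a block, 1322 genes were called in HCT116, 254 in opposite directions, 4015 for the difference between lines and 3559 for the mean effect, and SNORA5C in LoVo was 0.01303. In LoVo 5588 genes were called, and 11 and 12 lists, with the epithelial (adjusted p = 0.0859), hypoxia (0.0675) and fibroblast (0.0675) lists of LoVo past 0.05. Libraries with the same number deviated together at correlations of 0.0164 to 0.0852, so the numbers were not taken to pair them. Every library correlated best with its own number, a hint from the data and not the design. Few or no counts in a group limit the snoRNAs and HUNK in HCT116, and the cause of these low counts was not tested.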

Other observations

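The families below and both tests of the SLERT locus in LoVo were chosen only after the results were seen. In the LoVo libraries labelled SLERT knockdown, 21 of 27 keratins fell (median log2 fold change -1.08), and KRT4, KRT5, KRT38, KRT36, KRT71 and KRT1 had the smallest p. Of 7 MHC class II genes with CD74, 5 fell (median -1.47), among them CD74, HLA-DRA, HLA-DPA1 and CIITA, the class II transactivator. Of 19 collagens, 11 fell (median -0.79), among them COL3A1, COL17A1, COL13A1 and COL7A1. Of 17 aminoacyl tRNA synthetases, 9 rose (median 0.17), among them SARS1, LARS1 and IARS1, which respond to amino acid stress. These families were picked because members had been seen to change, so no p-value is given for them as groups, and the counts are those of single genes past the edgeR test. Keratin and HLA genes have near-identical copies that may share reads, so their single values are uncertain to that extent.

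Of 6 CXC chemokine ligands in LoVo, 4 rose (median 0.93), among them CXCL3, CXCL1 and CXCL2. Plexins and semaphorins were lower in 13 of 27 and higher in 1, HLA class I genes lower in 4 of 9, S100 genes higher in 4 of 12, and mucins higher in 1 and lower in 2 of 11.

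The counts of the SLERT locus did not fall in LoVo with knockdown, and 2 explanations were tested. Whether there were too few reads to see a fall by a factor of 2 was not settled. The lower end of the 95% interval of the log2 fold change of SNORA5C was -0.9178 with all 6 libraries, and it ran from -1.234 (without control 1) to -0.6188 (without control 3) with a library left out, below -1 in 5 of 6 cases. Whether the snoRNA reads in LoVo come from another RNA than SLERT was not settled. SNORA5A held 22.92% of the reads of both snoRNAs in LoVo (22 reads against 74 of SNORA5C) and 6.87% with overexpression in HCT116 (142 against 1926). By library, the shares ran from 7.69% to 43.75% and from 6.51% to 7.39% (exact permutation of the 9 libraries, two-sided, p = 0.0952). The HCT116 controls, with 0 reads of SNORA5A and 16 of SNORA5C, did not have the higher share. Both explanations and a knockdown without effect stay open.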
